A study of Mus musculus with 12 samples.

How the data were processed

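The series measured gene expression in bone marrow cells of 4- to 6-week-old mice, isolated per the labels' protocols with magnetic beads against B220 (CD45R), a surface protein of the B lineage. Total RNA of each sample was hybridised to 1 Affymetrix MOE430 2.0 array. The labels put 12 arrays in 4 groups of 3: wild type, mice with the Eµ-TTP-1 transgene, precancerous Eµ-Myc mice, and precancerous mice with both transgenes. TTP (tristetraprolin) is encoded by Zfp36. The labels call the samples of a group biological replicates, and all groups are littermates of the same cross. Sex is not given in the labels used here.

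The deposited values are GCRMA summaries of each probe set, per the submitters' processing notes, which give no version. GCRMA corrects the background, normalizes between arrays and summarises probes by a robust fit. The values themselves show that the authors deposited them as intensity on a linear scale, from a lowest value of 1.73 to a highest of 120125, with no centring per gene. The median intensity of an array was 10.9 to 13.9. Scanner files were not used here. Further steps by the authors are not given in the sources used here. Because GCRMA normalizes between arrays, a change in the total RNA of a cell cannot be seen, and probe sets without signal pile up at a low value, so that fold changes against them are lower bounds. For arrays, the number of arrays limits the precision.

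The analysis took log2 of the deposited intensity with no pseudocount. Of 45101 probe sets, the platform annotation used here gave 34958 a single gene symbol, 932 several symbols and 9211 none, and probe sets without a single symbol named no gene. Symbols were updated through Entrez identifiers in a RefSeq gene table of assembly GRCm38.p6, in which 34754 of the single-symbol probe sets were found. Gene positions were taken from this table only to find the neighbours of Pkm. Each of 18194 genes was represented by its probe set with the highest mean over all 12 arrays. A gene was tested when its log2 intensity was above 4 on at least 3 of the 12 arrays, whatever their group, which left 10287 genes and left out 7907. Where the mean of a group lay below that floor, the difference is given as at least a number of folds, computed against the floor.

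Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), on all 12 arrays with 4 group means and 8 residual degrees of freedom, and without covariates. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 10287 genes. All adjusted p-values for genes are from this limma fit unless another tool is named. Between wild-type and TTP arrays all 3 same-numbered pairs had residuals correlated above 0.1 (0.498, 0.664 and 0.821), which the labels do not explain. Arrays 1 and 2 correlated across numbers too (0.512 and 0.433). Both arrays numbered 3 stood apart from their groups in the same direction, which alone can give this pattern, so it is no clear sign of pairing. Errors beside log2 differences are standard errors of the fit, and errors beside group means are SD with n = 3. The contrasts were Myc over wild type, TTP over wild type, Myc TTP over Myc, Myc TTP over TTP, and the interaction, which is the TTP difference with Myc minus the TTP difference without it. Gene lists were fixed before the data were examined, 41 in number with 901 members, of which 732 were tested. They covered growth and metabolism, cell cycle, p53 and BCL2 family genes, mRNA decay and reported TTP targets, B-cell stages, signalling, stress and other bone marrow cell types. The 38 lists with at least 5 tested genes, the list of sex-linked genes apart, were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes. Beside it stand camera with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes. No list was called in any contrast with an estimated correlation.

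The genes named in the text were chosen by a rule fixed before the data were examined. For each contrast it takes the 8 largest rises and 8 largest falls among called genes whose 3 values in one group all lie above the 3 of the other, without immunoglobulin, T-cell receptor and sex-linked genes. It adds up to 4 members with the smallest p from each list that was called or had at least 3 called members, with at most 2 for other cell types, and always Myc and the ZFP36 family. Where fewer than 5 genes were called, the 5 genes with the smallest p in each direction are named as not passing. The text gives a part of the genes that this rule selects, and an item among them is not reported here. For the interaction it takes the 10 called genes with the smallest p, and as none was called the genes nearest to the threshold are named instead.

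The alternatives tried were no filter and a stricter floor of 6, all probe sets separately, the probe set with the largest SD, quantile normalization, a common median, eBayes without trend or with robust estimation, only the arrays of the groups compared, array weights, the replicate number as a block, each array left out in turn, a minimum of 2-fold, an adjusted p under 0.01 and an unmoderated linear model. After the data were seen, 3 further settings were added: leaving out the arrays labelled wild type 3 and TTP 3, on which Myc went against the label, leaving out all 4 arrays numbered 3, and, for TTP over wild type, the replicate number as a block on the wild-type and TTP arrays alone. The fit and camera were tested on simulated data, 10 draws for each contrast, with 200 of the 10287 genes changed. For Myc over wild type, with the residuals of the real arrays as noise, 39.1% of genes changed by 1 log2 unit were recovered, 84.8% of those changed by 2 and 92.0% of those changed by 3. For the interaction these shares were 15.4%, 69.7% and 83.9%. Unchanged genes called per draw averaged 0.1 for Myc over wild type, 1.4 for TTP over wild type, 404 for Myc TTP over Myc, 11.1 for Myc TTP over TTP and 3.8 for the interaction. The average of 404 is above the 200 genes changed. The residuals of all 12 arrays were shuffled over the groups in the same way for every contrast. Values for the 4 contrasts of 2 groups therefore differ only through the draws and are not a property of a contrast. In those draws no list was changed as a list, and camera with the preset correlation still called a mean of 9.2 of the 38 lists for Myc over wild type, 14.3 for TTP over wild type, 16.6 for Myc TTP over Myc, 15.8 for Myc TTP over TTP and 12.2 for the interaction. With independent noise the mean was between 0 and 0.2. Figures were drawn with matplotlib 3.10.9.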

Results

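Gene expression was measured on 12 arrays of B220-selected bone marrow cells from young littermate mice, 3 arrays in each of 4 groups. Wild-type mice were compared with mice that carry a TTP transgene, a Myc transgene, or both, each driven by the immunoglobulin heavy chain enhancer (Eµ), which directs expression to B cells. Eµ-Myc mice develop B-cell lymphoma, and the labels describe the Myc groups as precancerous. TTP binds AU-rich elements in the 3' untranslated regions of mRNAs and promotes their decay. The design asks how each transgene alters the B-cell transcriptome alone and how TTP alters it in the presence of Myc. Between 46.0% and 48.7% of the probe sets of an array had a log2 intensity above 4.

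The Myc probe set separated most arrays by their label, with 2 exceptions. Its intensity was 13361, 15451 and 8163 on the Myc arrays and 3617, 6801 and 10551 on the Myc TTP arrays. It was 805 and 819 on the arrays labelled wild type 1 and 2 but 6411 on the array labelled wild type 3, and 1060 and 1343 on those labelled TTP 1 and 2 but 11360 on the array labelled TTP 3. With all arrays, Myc over wild type was 2.88 ± 0.95 on the log2 scale and did not pass (adjusted p = 0.0615). Leaving out the arrays labelled wild type 3 and TTP 3, a choice made after the data were seen, gave 3.87 ± 0.40 (adjusted p = 0.000827). These arrays were chosen for their Myc signal, so the larger difference follows from the choice and is no support for the Myc labels.

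Zfp36, which encodes TTP, was not higher on arrays labelled with the TTP transgene. Its intensity was 1663, 892 and 918 on the wild-type arrays, 939, 952 and 878 on the TTP arrays, 623, 647 and 1022 on the Myc arrays, and 177, 393 and 579 on the Myc TTP arrays. The log2 difference was -0.26 ± 0.39 for TTP over wild type (adjusted p = 1.00) and -1.12 ± 0.39 for Myc TTP over Myc (adjusted p = 0.197). One probe set represented the gene, and whether it lies in the part of the mRNA that the transgene carries was not known here, so it does not check the TTP labels. Of the other family members, Zfp36l1 was -0.90 ± 0.30 in Myc over wild type (adjusted p = 0.0623) and Zfp36l2 was -0.65 ± 0.33 (adjusted p = 0.156).

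**Figure D1:**
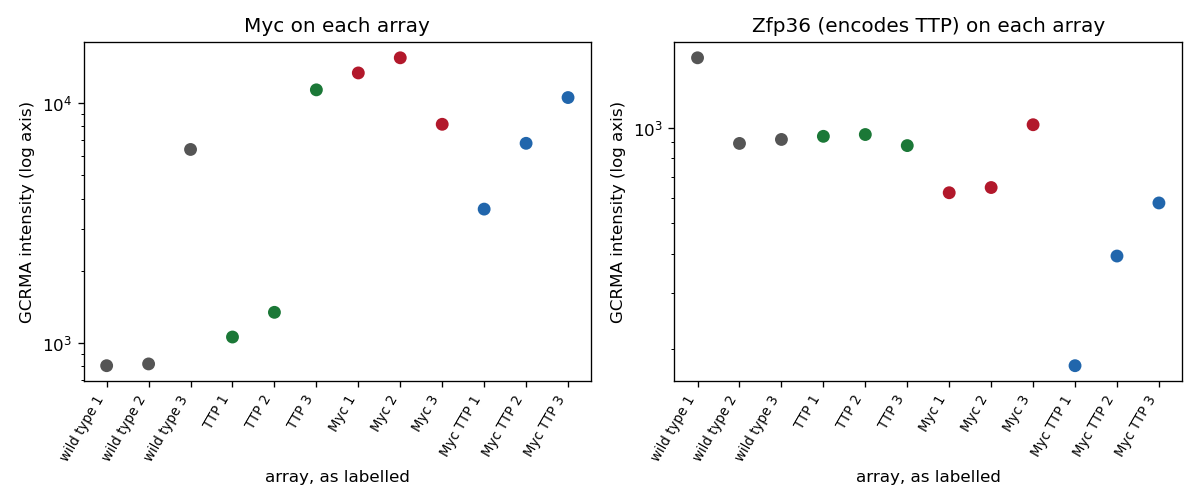
GCRMA intensity of Myc (left) and Zfp36 (right) on each of the 12 arrays, on a log axis, with 1 point per array coloured by its labelled group. Myc was 6411 on the array labelled wild type 3 and 11360 on that labelled TTP 3, against 805 to 1343 on the other 4 arrays without the Myc label.

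The arrays also differed in ways their groups do not explain. The first principal component held 73.5% of the variance, with the array labelled wild type 1 at -53.4 and wild type 2 at -64.0 on one side and Myc 1 at 76.2 and Myc 2 at 66.1 on the other. The arrays labelled wild type 3 (-7.65), TTP 3 (18.1) and Myc 3 (5.35) lay between them. Xist, which is transcribed from the inactive X chromosome of females, and at least 1 Y-linked probe set were both above the floor on 4 arrays, all of them numbered 3. Of the other 8 arrays, 7 had Xist alone and 1, Myc 1, had Y-linked signal alone. On the array labelled wild type 3, log2 Xist was 8.14 and log2 Kdm5d was 8.29, and on that labelled TTP 3 they were 11.75 and 8.78.

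**Figure D2:**
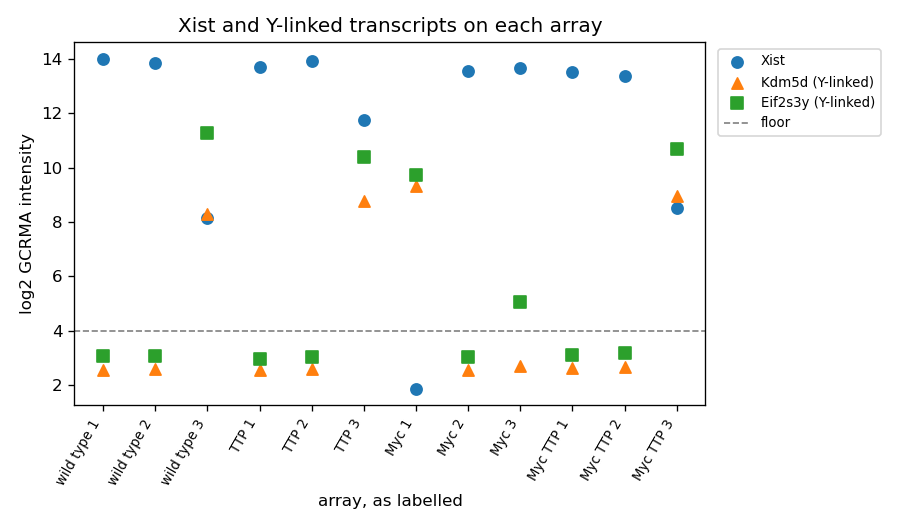
Log2 GCRMA intensity of Xist and of the Y-linked genes Kdm5d and Eif2s3y on each array, with the floor of 4 as a dashed line. The arrays numbered 3 have Xist and Eif2s3y above the floor together, with Eif2s3y at 5.05 on Myc 3.

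In the B220-selected cells of Eµ-Myc mice, a part of the genes of B-cell identity, of interferon and NF-κB signalling, and of other blood cells fell past the threshold, while few genes rose past it. The largest rise was in Chst7, a carbohydrate sulfotransferase, at least 5.78-fold (log2 6.53 ± 1.19 on the Myc arrays against a mean below the floor, SD, n = 3, adjusted p = 0.0479). Ltbp4, a latent TGF-β binding protein, rose by 2.71 ± 0.69 log2 units, Fstl1, a secreted follistatin-like glycoprotein, by 2.64 ± 0.60, and Fkbp11, a prolyl isomerase of the endoplasmic reticulum, by 2.26 ± 0.63. Genes of neutrophils were among the largest falls. The neutrophil surface protein Cd177 fell by 5.12 ± 1.45, the neutrophil collagenase Mmp8 by 5.03 ± 1.32 and the formyl peptide receptor Fpr2 by 4.67 ± 1.28. The erythroid and megakaryocytic factor Nfe2 fell by 4.85 ± 1.38. Among these 8 genes the adjusted p was at most 0.0490. The falls rest on Myc 1 and 2, as Myc 3 lay near wild type 3, with Cd177 at log2 11.07 against 11.34, Mmp8 at 10.06 against 10.89 and Fpr2 at 10.61 against 11.01. Without Myc 3, Cd177, Mmp8 and Fpr2 fell by 7.24, 6.90 and 6.53, and Nfe2 was at least 49.5-fold lower. Without Myc 1 these 4 genes were 3.70, 3.57, 3.35 and 3.91 log2 units lower, and without Myc 2 4.42, 4.61, 4.13 and 4.02 lower, and did not pass. Of the rises, without Myc 3 Chst7 was at least 9.32-fold higher, and Fstl1 rose by 3.33 and Fkbp11 by 2.88.

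In all, limma called 1135 of 10287 genes for Myc over wild type, 48 higher and 1087 lower. The 2 groups did not overlap for 4607 genes (44.8%, where chance gives 10% for independent genes). The array medians of the tested genes did not overlap either, at 8.96 to 8.98 on Myc and 9.14 to 9.29 on wild-type arrays. A shift of whole arrays can thus separate genes, and the 10% is no fair reference here. The median difference of all genes was -0.21, and it was 0.04 after quantile normalization and 0.05 with a common median, settings under which no gene was called. None was called either with an unmoderated linear model, no filter on low values, the probe set of largest SD, no intensity trend or an adjusted p under 0.01. The smallest adjusted p was 0.0479, close to the threshold, and 4218 genes had an unadjusted p under 0.05. The count was 3565 without the array labelled wild type 3, 3609 without TTP 3, 2151 without Myc 3, 1713 without TTP 2, and 0 without any 1 of the other 8 arrays. TTP and Myc TTP arrays are outside this contrast. Leaving out such an array keeps every difference and alters only the spread shared by the 4 groups. Without the arrays labelled wild type 3 and TTP 3, 4965 genes were called, 1439 higher and 3526 lower, and these held all 1135. Without the 4 arrays numbered 3, 5626 were called, 1891 higher and 3735 lower. Both settings were chosen after the data were seen.

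Ribosome biogenesis genes lay higher on the Myc arrays as a group, though no member passed over all genes. The median of the 39 tested members was 0.95, and 23 were higher when adjusted over the list alone. Wdr12, a component of the PeBoW complex that processes the large ribosomal subunit, was 1.25 ± 0.39 higher (adjusted p = 0.0553), and the nucleolar protein Nop58 was 0.85 ± 0.28 higher (adjusted p = 0.0622). The camera adjusted p of the list was 5.48e-19, with adjusted p = 0.463 with an estimated correlation and 0.0743 by fry. Without the arrays labelled wild type 3 and TTP 3, all 39 members were called higher. Genes of nucleotide and polyamine synthesis gave a median of 0.84 over 23 members (camera adjusted p = 1.27e-10, adjusted p = 0.463 with an estimated correlation). None passed over all genes, and adjusted over the list alone 17 were higher and 1 lower. Odc1, the rate-limiting enzyme of polyamine synthesis, was 0.68 ± 0.22 higher (adjusted p = 0.0614). Of 28 cytosolic ribosomal protein genes 1 passed, Rps6, which rose by 0.61 ± 0.17, and 0 were higher adjusted over the list alone. On the same arrays the markers of granulocytes had a median of -3.76 and those of erythroid cells a median of -3.33.

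Among B-cell genes the changes that passed were falls. Of 24 pro-B and pre-B cell genes 14 fell and 10 did not pass, with 21 lower adjusted over the list alone (median -1.60, camera adjusted p = 1.63e-06, adjusted p = 0.463 with an estimated correlation). Cd93, an early B-cell marker, fell by 1.84 ± 0.40, and Bst1, an ectoenzyme of bone marrow B-lineage cells, by 2.00 ± 0.46. Of 18 pan-B genes 12 fell, 16 adjusted over the list alone (median -0.73, camera adjusted p = 1.09e-05, adjusted p = 0.463 with an estimated correlation). They included the transcription factors Spib, which fell by 0.99 ± 0.21, Ikzf1, by 0.55 ± 0.13, and Tcf3, by 0.43 ± 0.10. Of 28 genes of mature and recirculating B cells 9 fell, 16 adjusted over the list alone (camera adjusted p = 0.000190, adjusted p = 0.463 with an estimated correlation). The receptor of the survival factor BAFF, Tnfrsf13c, fell by 1.65 ± 0.33, Cd40 by 2.37 ± 0.53, and the low-affinity IgE receptor Fcer2a by 3.02 ± 0.74. Of 25 genes of B-cell receptor signalling 7 fell, 15 adjusted over the list alone, among them the kinase Syk, by 0.81 ± 0.19 (camera adjusted p = 0.000388, adjusted p = 0.463 with an estimated correlation). Without Myc 3, Cd40 fell by 2.95 and Fcer2a by 3.81. Granulocyte markers fell on the same arrays, 8 of 18.

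Interferon and NF-κB genes also fell. Of 24 interferon response genes 16 fell, 22 adjusted over the list alone (median -2.15, camera adjusted p = 5.07e-07, adjusted p = 0.463 with an estimated correlation). Usp18, a protease that removes ISG15, was at least 10.4-fold lower, and Irf9, a subunit of the ISGF3 factor, fell by 1.59 ± 0.34. Of 15 NF-κB targets 10 fell, 13 adjusted over the list alone (camera adjusted p = 6.30e-05, adjusted p = 0.463 with an estimated correlation). The inhibitor Nfkbia fell by 1.53 ± 0.36 and Nfkb2 by 2.71 ± 0.66. Of 18 immediate early genes 7 fell and 1 rose, and adjusted over the list alone 12 were lower and 1 higher (camera adjusted p = 0.00750, adjusted p = 0.463 with an estimated correlation). Klf4, a transcription factor, fell by 3.26 ± 0.68, and the orphan receptor Nr4a2 was at least 2.18-fold higher. Of 16 CDK inhibitors and D and E cyclins, 2 rose and 2 fell, and adjusted over the list alone 3 were higher and 8 lower. The cyclin Ccnd2 fell by 2.31 ± 0.65, Ccnd3 by 1.03 ± 0.28, and Ccne1 rose by 0.66 ± 0.16. Without Myc 3, Nfkb2 fell by 3.50 and Klf4 by 3.99, and without Myc 1 Ccnd2 was 1.68 lower and did not pass. That list was not called (camera adjusted p = 0.922). Of 24 p53 targets 4 fell, among them Mdm2, which encodes the ligase that degrades p53, by 0.98 ± 0.25. Adjusted over the list alone 2 were higher and 8 lower, and the p53 list was not called (camera adjusted p = 0.922). On the same arrays granulocyte markers had a median of -3.76 and erythroid markers a median of -3.33.

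Markers of bone marrow cells other than B cells were lower on the Myc arrays. The B220 beads are meant to leave most of these cells behind, although plasmacytoid dendritic cells of mice also carry B220. Of 18 granulocyte genes 8 fell, 16 adjusted over the list alone, with a mean log2 level of 11.56, 11.93 and 11.09 on the wild-type arrays and 6.26, 7.35 and 10.88 on the Myc arrays (camera adjusted p = 0.000155, adjusted p = 0.463 with an estimated correlation). Mmp9, the neutrophil gelatinase, fell by 4.61 ± 1.18. Of 17 erythroid genes 1 fell, 12 adjusted over the list alone. This was Alas2, the first enzyme of heme synthesis in red cells, at least 6.79-fold lower (camera adjusted p = 0.00199, adjusted p = 0.4998 with an estimated correlation). Of 11 plasmacytoid dendritic cell genes 8 fell (camera adjusted p = 4.72e-05), of 13 NK-cell genes 3 (0.000940) and of 18 monocyte and macrophage genes 3 (0.000373), each with adjusted p = 0.463 with an estimated correlation. Adjusted over the list alone 11, 11 and 15 of them were lower. Gzma, a granule protease of cytotoxic cells, fell by 4.03 ± 1.00, and Lyz2, lysozyme of myeloid cells, by 2.77 ± 0.75. Without Myc 3, Gzma fell by 5.47 and Lyz2 by 3.83, and Mmp9 was at least 70.8-fold lower. Without Myc 1 these were 3.09, 2.05 and 3.57 log2 units lower, and without Myc 2 Mmp9 was 4.00 lower, and did not pass.

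Other lists of growth and metabolism were shifted upward relative to the other genes, with no member called over all genes or adjusted over the list alone. Translation factors had a median of 0.39 (camera adjusted p = 3.39e-08), mitochondrial import factors and chaperones 0.62 (1.35e-08), aminoacyl-tRNA synthetases 0.49 (1.03e-05), oxidative phosphorylation 0.16 (1.09e-05), DNA replication 0.15 (2.45e-05), glycolysis 0.33 (0.000940), mRNA decay machinery 0.11 (0.00756) and heat shock genes 0.14 (0.0487). Each of these had adjusted p = 0.463 with an estimated correlation. Mitosis genes had a median of 0.01 (camera adjusted p = 0.0281, adjusted p = 0.677 with an estimated correlation). The cytosolic ribosomal protein list was also called (camera adjusted p = 0.00167, adjusted p = 0.463 with an estimated correlation). After quantile normalization it was not called, at 0.0898, nor were the heat shock genes, at 0.09998. Of 24 autophagy and lysosome genes 10 fell, 17 adjusted over the list alone, of 11 plasma cell genes 5 and 9, and of 18 integrin, adhesion and homing genes 7 and 11. Their camera adjusted p was 0.000396, 0.00585 and 0.00750. Of 9 stem and progenitor genes 0 fell, 7 adjusted over the list alone, and of 5 basophil and mast cell genes 2 and 4 (camera adjusted p = 0.0281 and 0.0294). These 5 lists had adjusted p = 0.463 with an estimated correlation. Lists not called were T-cell genes (camera adjusted p = 0.0560), reported TTP targets (0.598), the MYC and MAX network (0.728), BCL2 family (0.775), stress response (0.728), germinal centre (0.213) and megakaryocyte genes (0.237). Fry called 3 of these downward, T-cell genes (adjusted p = 0.0360), the MYC and MAX network (0.0284) and stress response (0.0284). In them 2 of 8, 2 of 12 and 3 of 17 genes fell, and adjusted over the list alone 5 were lower in each, with 1 higher in the MYC and MAX network. In total camera called 29 of 38 lists in this contrast, 12 upward and 17 downward. The count was 28 without the arrays labelled wild type 3 and TTP 3 and 28 without the 4 arrays numbered 3. In simulated arrays without list changes the highest number was 21 for this contrast. It was 29 for Myc TTP over Myc, whose arrays were simulated in the same way, so 29 lists do not exceed what the real residuals gave as noise. These residuals include the deviations of wild type 3, TTP 3 and Myc 3 from their groups, so they may hold more than noise.

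**Figure D3:**
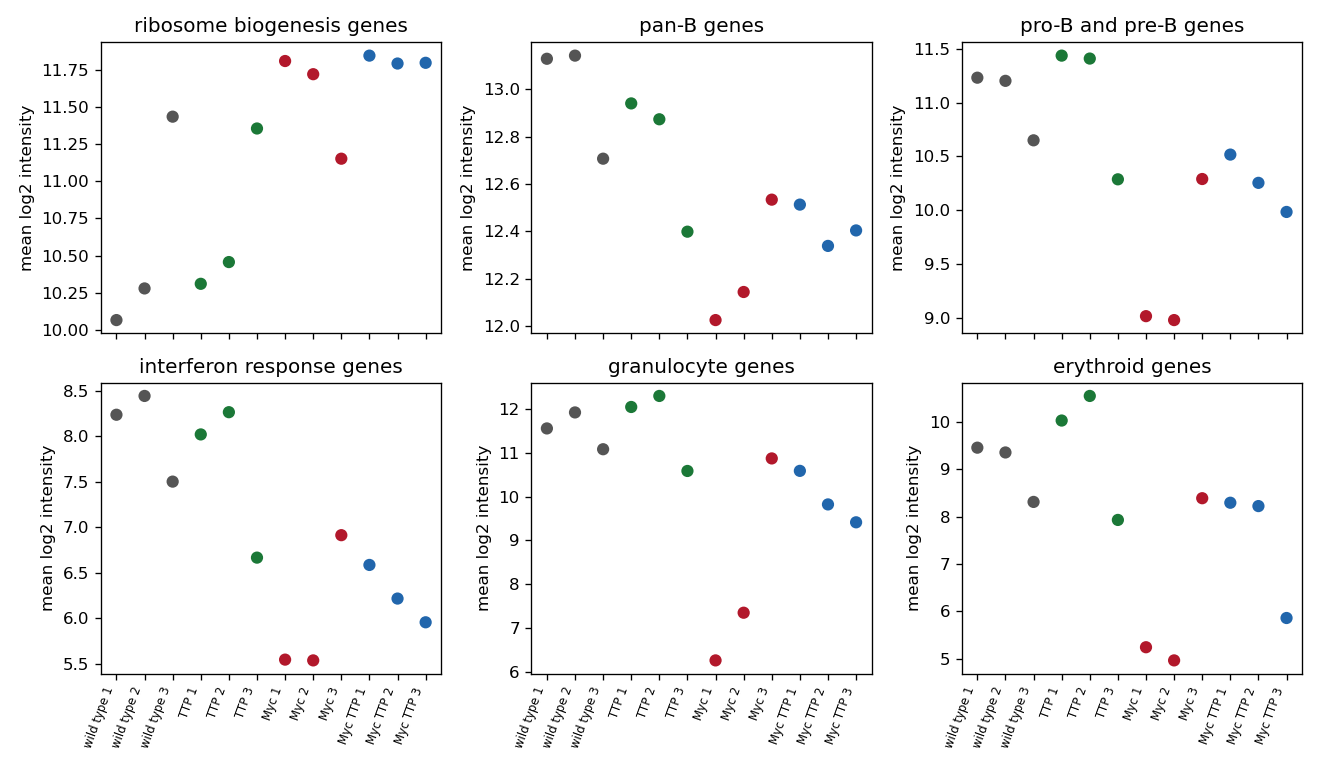
Mean log2 intensity of the tested members of 6 gene lists on each of the 12 arrays, with 1 point per array coloured by its labelled group, and with a separate vertical range in each panel that does not start at 0. Ribosome biogenesis genes were at 10.07 and 10.28 on the arrays labelled wild type 1 and 2, 11.44 on wild type 3, and 11.81, 11.72 and 11.15 on the Myc arrays.

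Between Myc TTP and TTP arrays no single gene passed. Nop14, a factor of small ribosomal subunit assembly, was 1.32 ± 0.29 higher in Myc TTP than in TTP arrays, and the mitochondrial folate enzyme Mthfd2 1.23 ± 0.31 higher. Fcer2a was 3.23 ± 0.74 lower, and Csf1r, the receptor of macrophage growth factor, 1.92 ± 0.38 lower. The adjusted p of each was 0.0607, the smallest in this contrast. Without TTP 3, Fcer2a fell by 3.96 (adjusted p = 0.0130), and without TTP 2 it was 2.56 lower and did not pass. Of the genes nearest to the threshold, Adat3, a subunit of a tRNA adenosine deaminase, was 1.78 ± 0.28 higher and the podosome adaptor Sh3pxd2a 1.86 ± 0.30 lower. Another of them, Ube2d-ps, is a pseudogene whose probe set could also bind transcripts of its parent family, so its difference of 1.28 ± 0.17 is uncertain.

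For Myc TTP over TTP, limma called 0 of 10287 genes, with 3707 at an unadjusted p under 0.05, and an unmoderated linear model called 5. The groups did not overlap for 3698 genes (35.9%, where chance gives 10% for independent genes). Genes moved together, with 73.5% of the variance in the first principal component, so the 10% is no fair reference. The count was 3951 without the array labelled TTP 3, 1907 without wild type 3 and 7 without Myc 3. Wild type 3 and Myc 3 are outside this contrast, so leaving them out alters only the shared spread. With both arrays labelled wild type 3 and TTP 3 left out after the data were seen, 4412 genes were called, 2158 higher and 2254 lower, and without the 4 arrays numbered 3, 4682, 2439 higher and 2243 lower.

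By group, ribosome biogenesis genes had a median of 1.13 in Myc TTP over TTP, with 34 of 39 higher adjusted over the list alone (camera adjusted p = 4.09e-09, adjusted p = 0.367 with an estimated correlation). Of 34 DNA replication genes 18 were higher adjusted over the list alone, and of 34 mitosis genes likewise 18. Their camera adjusted p was 9.46e-06 and 1.41e-05, each with adjusted p = 0.367 with an estimated correlation. Mcm10, which loads factors at replication origins, was 0.92 ± 0.23 higher (adjusted p = 0.0607). Of 35 genes of the mRNA decay machinery 18 were higher adjusted over the list alone, among them Exosc3 and Exosc10 of the RNA exosome at 0.76 ± 0.15 and 0.63 ± 0.13 (camera adjusted p = 0.000128, adjusted p = 0.367 with an estimated correlation, fry adjusted p = 0.0346). Of 28 mature and recirculating B-cell genes 12 were lower adjusted over the list alone, and of 24 interferon response genes 8. The camera adjusted p of both was 4.09e-09, with adjusted p = 0.367 with an estimated correlation. The complement receptor Cr2 was at least 12.5-fold lower and Egr3, an immediate early factor, at least 12.1-fold lower (adjusted p = 0.0607 for both). For Cr2 the bound was 7.06-fold without TTP 2 and, passing, 24.6-fold without TTP 3. Over all genes, no member of these lists passed. Erythroid markers had a median of -2.24 and granulocyte markers a median of -1.89 on the same arrays. In all, camera called 31 lists, 11 upward and 20 downward. Simulated arrays without list changes gave up to 26 in this contrast and up to 29 in Myc TTP over Myc, simulated in the same way. Camera called 30 without the arrays labelled wild type 3 and TTP 3 and 31 without the 4 arrays numbered 3. After quantile normalization T-cell genes were not called (camera adjusted p = 0.0807), and with a common median cytosolic ribosomal protein genes were not (0.0888).

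The 2 Myc contrasts share no arrays, and across the 10287 genes their log2 differences had a Pearson r of 0.878 and a Spearman rho of 0.841. Genes are not independent replicates, and no p is given. Of the 1135 genes called in Myc over wild type, 91.7% had the same sign in Myc TTP over TTP. Without the arrays labelled wild type 3 and TTP 3, 1214 genes were called higher and 1996 lower in both contrasts, where independent lists of those sizes would share 302 and 773, and 6 were called in opposite directions. Both lists use the same residual spread per gene, so a gene of small spread tends to be called in both. These arrays were also left out for their Myc signal, after the data were seen. Independent lists are thus no fair reference here.

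Between TTP and wild-type arrays no gene passed. Pkm, the pyruvate kinase of glycolysis, had a log2 level of 12.94 ± 0.10 on the TTP arrays against 11.50 ± 1.10 on the wild-type arrays (SD, n = 3), a difference of 1.44 ± 0.40 that did not pass (adjusted p = 1.00). Its intensity was 1615 and 2194 on the arrays labelled wild type 1 and 2, 6887 on wild type 3, and 7274 to 8217 on the TTP arrays. Jchain, which joins IgM and IgA polymers in plasma cells, was 2.92 ± 0.63 lower, and Eaf2, a transcription elongation factor, 0.80 ± 0.17 lower, with the same adjusted p. Without the array labelled wild type 3, 1 gene was called, Pkm, at 2.06 ± 0.16 (adjusted p = 0.00157). Pkm was also the 1 gene called without the arrays labelled wild type 3 and TTP 3, where it rose by 2.12 ± 0.17 (adjusted p = 0.00321), and without all 4 arrays numbered 3 (adjusted p = 0.00274). These last 2 settings were chosen after the data were seen, as was a fit on the wild-type and TTP arrays alone with the replicate number as a block, which left 2 residual degrees of freedom and called 4 genes, all lower. They were Jchain (-2.92 ± 0.38, adjusted p = 0.0372), the immunoglobulin heavy chain gene Igha (-1.88 ± 0.24, adjusted p = 0.0372), an immunoglobulin kappa variable gene (-2.34 ± 0.26, adjusted p = 0.0300) and Slc15a2, a peptide transporter (-1.57 ± 0.19, adjusted p = 0.0348), named after their values were seen. In that fit camera called 18 lists, 11 upward and 7 downward, with 0 called with an estimated correlation and 0 by fry. List means had the same sign in all 3 same-numbered pairs for 4 of 38 lists. Between the arrays numbered 3 every list was lower on TTP 3, as was the median of all tested genes (8.93 against 9.24). A list could thus agree only by being lower, and random signs give no reference for this count. The 4 lists were pan-B (-0.19, -0.27 and -0.31), plasma cell (-0.41, -0.33 and -0.58), plasmacytoid dendritic cell (-0.55, -0.27 and -0.88) and interferon response genes (-0.22, -0.18 and -0.84). Of the 11 lists called with all 12 arrays, 3 were among these.

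For TTP over wild type, limma called 0 of 10287 genes with all arrays, with 149 at an unadjusted p under 0.05, and the unmoderated linear model called 0. The groups did not overlap for 437 genes (4.25%, where chance gives 10% for independent genes). As genes moved together, the 10% is no fair reference here either. Camera called 11 lists, 8 upward and 3 downward, and the count was 6 without the array labelled wild type 1 and 18 without wild type 3. It was 13 without the arrays labelled wild type 3 and TTP 3 and 16 without the 4 arrays numbered 3. The 3 lists called downward were pan-B genes (median -0.24, camera adjusted p = 0.000153), plasmacytoid dendritic cell genes (-0.45, 0.0232) and interferon response genes (-0.44, 0.0325), and glycolysis genes were among those called upward (0.12, 0.000609), each with adjusted p = 0.936 with an estimated correlation. Of the 18, 11, 24 and 14 members of these lists 0 passed over all genes or adjusted over the list alone, and in the same contrast the erythroid list had a median of 0.43 (camera adjusted p = 0.00223, adjusted p = 0.936 with an estimated correlation). In simulated arrays without list changes camera called up to 24 lists in this contrast, and fry called 0 in the real arrays. After quantile normalization ribosome biogenesis (camera adjusted p = 0.0553), translation factors (0.0832), mitochondrial import (0.109) and monocyte genes (0.0910) were not called. Of 15 genes reported as TTP targets 0 were called, and the list, with a median of -0.19, did not pass (camera adjusted p = 0.791).

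Between Myc TTP and Myc arrays no gene passed. Psme4, an activator of the proteasome, was 0.76 ± 0.11 higher in Myc TTP than in Myc arrays, Rsph1, a radial spoke protein, 1.27 ± 0.19 higher, and Slc37a1, a sugar-phosphate exchanger, 1.41 ± 0.21 higher (adjusted p = 0.139 for each). Ccnd1, cyclin D1, a G1 cyclin on the list of reported TTP targets, was 1.83 ± 0.40 lower (adjusted p = 0.172), with intensities of 1191, 716 and 303 on the Myc arrays and 184, 168 and 186 on the Myc TTP arrays. S100a6, a calcium-binding protein, was 2.31 ± 0.53 lower (adjusted p = 0.172). Myc itself was -0.90 ± 0.95 (adjusted p = 0.577).

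For Myc TTP over Myc, limma called 0 of 10287 genes, with 1966 at an unadjusted p under 0.05, and the unmoderated linear model called 16. The groups did not overlap for 3466 genes (33.7%, where chance gives 10% for independent genes). The array medians of the tested genes did not overlap either, at 9.10 to 9.38 on Myc TTP and 8.96 to 8.98 on Myc arrays. A shift of whole arrays can thus separate genes, and the 10% is no fair reference here. The median difference of all genes was 0.27 on the deposited scale, 0.05 after quantile normalization and 0.01 with a common median. Without the array labelled Myc 3, 28 genes were called, and without TTP 3, 1. Leaving out the arrays labelled wild type 3 and TTP 3 gave 1 called gene, Slc37a1, which rose by 1.41 ± 0.15 (adjusted p = 0.0431). These arrays are outside this contrast, so the difference of Slc37a1 was unchanged and only the shared spread altered. Leaving out all 4 arrays numbered 3 gave 1514, 1455 higher and 59 lower. Both settings were chosen after the data were seen.

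Of the gene lists, camera called 5 for Myc TTP over Myc, DNA replication and mitosis upward and 3 downward, fewer than the 29 reached in simulated arrays without list changes. The count was 10 without the array labelled Myc 1, 8 without Myc 2 and 8 without Myc 3. It was 6 without the arrays labelled wild type 3 and TTP 3 and 10 without the 4 arrays numbered 3. Of 34 DNA replication genes 7 were higher adjusted over the list alone and 0 over all genes, such as the DNA ligase Lig1 at 0.48 ± 0.11 (adjusted p = 0.172). The list median was 0.32, and 0.06 with a common median (camera adjusted p = 0.0169, adjusted p = 0.989 with an estimated correlation). Of 34 mitosis genes 1 was higher adjusted over the list alone and 0 over all genes, with the phosphatase Cdc25b at 0.59 ± 0.12 (list camera adjusted p = 0.00566, adjusted p = 0.989 with an estimated correlation). The reported TTP targets were called downward relative to other genes (camera adjusted p = 0.00358, adjusted p = 0.989 with an estimated correlation). Of the 15 members 0 passed over all genes and 1 was lower adjusted over the list alone. Their median was 0.03 and their mean -0.12, and with a common median the list median was -0.24 and the camera adjusted p 0.149, and after quantile normalization it was 0.0538. Mature and recirculating B-cell genes (median 0.10, camera adjusted p = 0.000321) and immediate early genes (median 0.07, camera adjusted p = 0.00105) were also called downward relative to the other genes, although their medians were above 0. With a common median they were -0.17 and -0.19. In that setting DNA replication (camera adjusted p = 0.312), mitosis (0.667) and immediate early genes (0.0666) were not called, and mature B-cell genes were (0.0118). Both mature B-cell and immediate early genes had adjusted p = 0.989 with an estimated correlation, and 0 of their 28 and 18 members passed over all genes or adjusted over the list alone. On the same arrays granulocyte markers had a median of 2.07 and erythroid markers a median of 1.60, and neither list was called (camera adjusted p = 0.232 and 0.874).

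Across genes, the 2 TTP contrasts, which share no arrays, had a Pearson r of 0.0954 and a Spearman rho of 0.0485. The value of r was -0.0138 without the array labelled wild type 3, -0.0309 without TTP 1, -0.0710 without TTP 2 and 0.272 without TTP 3. The value of rho was -0.000804 without wild type 1, -0.0349 without TTP 1, -0.0593 without TTP 2 and -0.0534 without Myc 3, and it was 0.146 without TTP 3 and 0.139 without Myc 1.

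The interaction asks whether the TTP difference depends on Myc. Slc37a1 (1.80 ± 0.30), Pogk (1.41 ± 0.24) and Psme4 (0.86 ± 0.15) were among the positive values with the smallest p, and S100a6 (-2.73 ± 0.74) was among the negative ones, none of them passing (adjusted p = 0.358 for each). For Ccnd1 it was -1.60 ± 0.56 with the same adjusted p. Limma called 0 of 10287 genes, with 1351 at an unadjusted p under 0.05, and the unmoderated linear model called 0. Without the arrays labelled wild type 3 and TTP 3 the count was again 0, and without the 4 arrays numbered 3 it was 235, 226 higher and 9 lower, both chosen after the data were seen. The median interaction of all genes was 0.34, and 0.04 after quantile normalization. Camera called 6 lists, 1 upward and 5 downward, against up to 30 in simulated arrays without list changes. With an estimated correlation 0 were called (smallest adjusted p = 0.969 with an estimated correlation), and after quantile normalization none of these 6 stayed under the threshold. The count was 3 without the array labelled TTP 2, 3 without Myc TTP 2, 11 without TTP 3 and 13 without Myc 3. It was 4 without the arrays labelled wild type 3 and TTP 3 and 12 without the 4 arrays numbered 3.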

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

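The list tests of the interaction were planned before the data were examined. For 6 lists the difference that accompanied the TTP transgene differed with Myc by the camera test of the interaction. Mitosis genes were shifted upward relative to the other genes (adjusted p = 0.0233, median 0.37). Shifted downward were ribosome biogenesis genes (0.00838, median 0.15), translation factors (0.0141, median -0.05), reported TTP targets (0.0141, median 0.15), mature and recirculating B-cell genes (0.0141, median 0.18) and monocyte and macrophage genes (0.0436, median 0.40). The median of all genes was 0.34. Of the 5 lists shifted downward 4 had medians above 0, that of monocyte and macrophage genes, with a mean of 0.32, above the median of all genes, and translation factors had a mean of 0.03 beside a median below 0. Reported TTP targets had a mean of -0.08. After quantile normalization the medians of ribosome biogenesis genes, reported TTP targets and mature B-cell genes were -0.09, -0.05 and -0.04, and 0 of the 6 lists were called. With a common median 1 of them, translation factors, was called (0.0163). No member of these lists was called as a gene, and all 6 had adjusted p = 0.969 with an estimated correlation.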

How the results depend on the processing

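Leaving out the arrays labelled wild type 3 and TTP 3, leaving out the 4 arrays numbered 3, and the block on wild-type and TTP arrays alone were chosen after the data were seen, and the other settings were planned. The number of arrays limits precision, and signal near background limits fold changes of dim genes. The cause of the changes below was not tested, except where a setting removes arrays or tightens the threshold by construction.

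For Myc over wild type, 1135 genes were called. The count was 0 with no filter on low values, with the probe set of largest SD, after quantile normalization, with a common median, without an intensity trend, at an adjusted p under 0.01 and with an unmoderated linear model. It was 2 with all probe sets separately, 736 with at least 2-fold, 2110 with only the groups compared, 6335 with array weights, 4965 without the arrays labelled wild type 3 and TTP 3, and 5626 without the 4 numbered 3. It was within 1.5 times with the stricter floor (1442) and robust estimation (1102). Leaving out 1 array gave 0 to 3609. Signs were compared in all settings but all probe sets separately and only the groups compared. Those of the 1135 genes that were tested kept their sign, apart from 8 with the probe set of largest SD.

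For TTP over wild type the count of 0 became 1 with all probe sets separately, 2 with array weights, 1 without the arrays labelled wild type 3 and TTP 3, 1 without the 4 numbered 3, and 0 to 1 without 1 array. For Myc TTP over Myc the count of 0 became 1 with a common median, 3110 with array weights, 16 with an unmoderated linear model, 1 without the arrays labelled wild type 3 and TTP 3, 1514 without the 4 numbered 3, and 0 to 28 without 1 array. For Myc TTP over TTP the count of 0 became 1 without an intensity trend, 6879 with array weights, 5 with an unmoderated linear model, 4412 without the arrays labelled wild type 3 and TTP 3, 4682 without the 4 numbered 3, and 0 to 3951 without 1 array. For the interaction the count of 0 became 1 with all probe sets separately, 176 with array weights and 235 without the 4 numbered 3, and it stayed 0 without any 1 array. Array weights were 0.288 for the array labelled wild type 3 and 0.167 for TTP 3, but 8.52 for Myc TTP 2, beside 0.521 and 0.713 for Myc TTP 1 and 3, and 3.50 for TTP 1.

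Gene lists called were 29, 11, 5, 31 and 6 in the 5 contrasts in the order above. With a correlation estimated per list all 5 counts were 0, and fry called 19, 0, 2, 2 and 2. Quantile normalization gave 7 for TTP over wild type and 8 for Myc TTP over Myc. Leaving out the 4 arrays numbered 3 gave 10 for Myc TTP over Myc and 12 for the interaction. Leaving out 1 array gave 27 to 30, 6 to 18, 4 to 10, 29 to 32 and 3 to 13.

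The replicate numbers are in the labels but did not pair the arrays over all groups: of 18 same-numbered pairs 7 had residuals correlated above 0.1, from -0.651 to 0.821, and 6 of 12 arrays correlated best with an array of their own number. With the number as a replicate block, 0 genes were called for Myc over wild type, and the list counts were 28, 11, 6, 31 and 5. It changed no other count of genes. Between wild-type and TTP arrays all 3 same-numbered pairs correlated above 0.1, and a block on these 6 arrays alone gave 4 genes, all lower, and 18 lists.

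Myc in Myc over wild type, at 2.88, passed with array weights (3.84), without the arrays labelled wild type 3 and TTP 3 (3.87) and without the 4 numbered 3 (4.15), with 2.38 to 3.87 without 1 array. In Myc TTP over TTP it passed in the same settings at 2.49, 2.42 and 2.06, with 0.71 to 2.42 without 1 array. Wild type 3 and TTP 3 were left out because of their Myc signal, so passing without them is no independent support for Myc in these 2 contrasts. Without the 4 numbered 3 Myc passed in Myc TTP over Myc at -1.53 and in the interaction at -2.09. Of the arrays left out, Myc 3 had the lowest Myc intensity of its group (8163) and Myc TTP 3 the highest of its own (10551). The interaction also left out wild type 3 and TTP 3. Passing there is thus no independent support for a lower Myc with TTP. Zfp36 passed with array weights in Myc over wild type (-0.79), Myc TTP over Myc (-0.79) and Myc TTP over TTP (-1.28). Without the 4 numbered 3 it passed in Myc TTP over Myc (-1.27) and Myc TTP over TTP (-1.84), and in the latter also without the arrays labelled wild type 3 and TTP 3 (-1.46), with -1.81 to -0.95 without 1 array. In TTP over wild type, values that did not pass changed sign: Myc was -0.44 without the array labelled TTP 3 (-0.44 to 1.64 over all arrays), and Zfp36 was 0.028 without wild type 1 (-0.42 to 0.028).

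The correlation across genes of the 2 Myc contrasts was r = 0.878 and rho = 0.841. With no filter it was 0.852 and 0.646, without the arrays labelled wild type 3 and TTP 3 it was 0.913 and 0.895, and without the 4 numbered 3 rho was 0.889. Leaving out 1 array gave r from 0.837 to 0.899 and rho from 0.783 to 0.881. For the 2 TTP contrasts r = 0.0954 and rho = 0.0485. Without the arrays labelled wild type 3 and TTP 3 they were 0.220 and 0.165, and without the 4 numbered 3 they were 0.252 and 0.133. With no filter rho was -0.129. Without 1 array r was -0.0710 to 0.272, with -0.0138 without wild type 3, -0.0309 without TTP 1 and -0.0710 without TTP 2. The range of rho was -0.0593 to 0.146, with -0.000804 without wild type 1, -0.0349 without TTP 1, -0.0593 without TTP 2 and -0.0534 without Myc 3.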

Other observations

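All settings and tests in this part were chosen after the values were seen, apart from the counts of genes and lists with all arrays. Without the 4 arrays numbered 3, which leaves 2 arrays in each group, genes of other blood cells were higher in Myc TTP than in Myc arrays. Of 18 granulocyte genes 16 rose (median 3.76), with 16 higher adjusted over the list alone, and of 17 erythroid genes 14 rose (median 3.78), with 15 adjusted over the list alone. Their camera adjusted p was 4.93e-13, with adjusted p = 0.749 with an estimated correlation, and 5.42e-18, with adjusted p = 0.494 with an estimated correlation. On the omitted array Myc 3, by contrast, granulocyte genes had a mean log2 level of 10.88 and erythroid genes 8.39, above all 3 Myc TTP arrays (10.59, 9.82 and 9.41, and 8.29, 8.22 and 5.86), and with all arrays neither list was called (camera adjusted p = 0.232 and 0.874). Without the 4 arrays, Klf1, a transcription factor of red cell precursors, was at least 30.3-fold higher, and Mpo, myeloperoxidase of granules, rose by 5.28 ± 0.53. Of 24 pro-B and pre-B genes 14 rose, 17 adjusted over the list alone (median 1.03, camera adjusted p = 5.90e-09, adjusted p = 0.494 with an estimated correlation). With all arrays 0 of the 24 passed, 3 adjusted over the list alone, and the list was not called (median 0.56, camera adjusted p = 0.275), and its mean log2 level on Myc 3, 10.29, lay above those on Myc TTP 2 and 3, 10.25 and 9.98. Without the 4 arrays Ccnd1 fell by 2.39 ± 0.30 and Chst7 by 3.21 ± 0.29. In the interaction of the same arrays Vpreb1, a surrogate light chain of the pre-B receptor, was 2.82 ± 0.22 (adjusted p = 0.000595), and 11 of 24 pro-B and pre-B genes and 13 of 18 granulocyte genes were higher.

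Xist and a Y-linked probe set were above the floor together on 4 arrays, all numbered 3. Xist was at 2.08% of its mean on the arrays with Xist alone on the array labelled wild type 3, 2.69% on Myc TTP 3, 25.4% on TTP 3 and 97.0% on Myc 3. Against Myc 1, the array with Y-linked signal alone, Kdm5d was at 48.8%, 78.3% and 68.3% on the arrays labelled wild type 3, Myc TTP 3 and TTP 3, while Eif2s3y was at 296%, 196% and 161%. On Myc 3 Kdm5d was below the floor and Eif2s3y at 3.92%. As the Y-linked genes disagree, these percentages do not measure a share of male RNA.

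On the first principal component the arrays labelled wild type 3 and TTP 3 lay between the other arrays of their groups and Myc 1 and 2, while TTP 3 lay beyond Myc 3. A single wrong label, with RNA of 1 animal alone, is argued against by Xist and Y-linked signal together on both of these 2 arrays, though RNA mostly of 1 male with a small admixture stays open for wild type 3. An offset in 1 direction on all arrays numbered 3 is argued against by residuals, whose correlation was as low as -0.651 between 1 pair, but wild type 3, TTP 3 and Myc 3 were more alike (r = 0.992, 0.992 and 0.994) than each was to the other arrays of its group (0.937 to 0.970), so a profile towards which these arrays converge stays open. A mixture in 1 proportion of RNA like the other arrays without Myc and RNA like Myc 1 and 2 was not decided. On wild type 3 genes higher and lower in Myc gave shares of 0.613 and 0.552, a difference of 0.0616 (0.0384 to 0.0760). For TTP 3 the difference was -0.292 (-0.308 to -0.275), only just inside the limit. The limit of 0.300 came from the held-out array wild type 1, and it is so wide that the test is weak for both arrays. Xist, at 2.08% on wild type 3, was far below its level on wild type 1 and 2 and TTP 1 and 2. The shares on wild type 3 would thus need RNA like those arrays but with little Xist. Whether RNA was pooled from several animals is not given in the sources used here, and an early Myc-like state of single animals was not tested.

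Markers of other bone marrow cells were lower on the Myc than on the wild-type arrays, with a median of -3.83 for granulocyte, -3.56 for erythroid, -3.03 for NK-cell, -2.21 for stem and progenitor, -2.17 for plasmacytoid dendritic cell and -1.61 for monocyte genes above a log2 level of 6. The bootstrap intervals of these 6 lists left a gap of 0.333, between monocyte genes (-2.27 to -1.39) and erythroid genes (-3.91 to -2.60). This does not decide on a single smaller share of all other cells in the B220 selection. Equal falls would follow from it only for markers that B cells do not express, which was not tested, and the bootstrap drew genes, not arrays. The pan-B genes had a median of -0.73 (-0.90 to -0.55, from the same bootstrap over genes). Fewer other cells would raise those pan-B genes that B cells express more than other cells do. Only for such genes is a smaller share of other cells argued against as the source of the fall. Which members these are was not tested. A single share stays open, as do separate changes in the share of each cell type, which could come from the selection or from the marrow of the animals and were not tested.

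Pkm separated the 6 arrays labelled with the TTP transgene, at 7274 to 9260, from the 6 without it, at 1615 to 6887, with a mean log2 difference of 1.23, and it was the largest of 10 such genes, where the median over all splits was 4. In the first test, 49 of the 462 splits of the 12 arrays into 6 and 6 gave a separated gene with as large a difference, so chance was not excluded. A second test, added after the result of the first was seen, relabelled TTP within the Myc and the other arrays, and 8 of 200 relabellings gave as large a difference, with 1.19 the highest below it. A shift of the whole chromosome segment by about the Pkm difference is argued against, as the 20 nearest tested genes had a median of 0.0789 (0.0239 to 0.159, SD 0.217), while a smaller shift of the region stays open. An effect of the transgene may be weighed only as a hypothesis, since the first of the 2 tests of chance leaves it open.

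The 6 arrays of a contrast give 10 splits into 3 and 3, the real one included, too few for a share under 0.05. For Myc over wild type the real split called 1135 genes and the highest other 0, with 1 of the 10 as large, and 29 lists against 27, with 1 as large. For TTP over wild type it called 0 genes against 30 and 11 lists against 24, with 5 as large in lists. For Myc TTP over Myc it called 0 genes against 8 and 5 lists against 22, with 10 as large in lists. For Myc TTP over TTP it called 0 genes against 1, and 31 lists against 27, with 1 as large in lists. For the interaction, 90 of 100 splits, the real one among them, called at least the real 6 lists, with 29 the highest other, so chance was not excluded for the lists. In genes, the real count of 0 in these 4 contrasts makes all splits as large by construction, 10 of 10 and, for the interaction, 100 of 100 with 21 the highest other, so these counts say nothing about chance. Of the 10 splits for TTP over wild type, 4 part all 3 same-numbered pairs, and of these the real one called 11 lists and the others at most 6 lists and 0 genes. The 6 that part 1 pair called 7 to 24 lists and up to 30 genes. The split with 30 genes put the arrays labelled wild type 3 and TTP 3, whose residuals correlated at 0.821, together with wild type 1, and its count points to a structure of the samples other than the groups.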
